A study of Caenorhabditis elegans with 2 samples.

How the data were processed

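Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans hermaphrodites, L4 larvae taken 52 h after synchronization at the starved first larval stage, per the labels. The strain, OP383, carries an inserted oef-1 gene (sequence name F49E8.2) whose product ends in a GFP-FLAG tag, and DNA bound to the protein was recovered with an antibody against GFP after sonication. There was 1 group of 2 samples, which the labels number as biological replicates 3 and 4.

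The values analysed here are peak lists, per the README texts among the deposited files. For each replicate, the authors deposited a candidate list made from that replicate's alignment and 1 control file shared by both replicates. A pooled candidate list was made from both alignments together and the same control. From these, the authors derived an optimal list with the irreproducible discovery rate (IDR), which keeps peaks that rank alike in replicates. The candidate lists hold weak peaks and background on purpose, as input to IDR. Each list came on ce10 and on ce11 coordinates. The peak caller, the aligner, their versions and the read depth are not given in the sources used here, so the depth behind each peak is unknown. The control alignment was not analysed here, and no sample of an untagged strain was used.

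Each peak in the deposited lists has a signal value, whose scale is not stated, and the −log10 of a q-value. The signal was used only to describe, rank and filter peaks within 1 list. The −log10 q-value was 2.75 for each of the 1339 peaks of the optimal list on ce11, the highest value in the pooled list, and was not used to rank. The optimal peaks were the 1339 pooled candidates with the highest signal. In 24 rows of the optimal list a peak had the same interval as another row and a different summit, and each summit was counted.

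The ce11 lists were set against the WBcel235 genome and its Ensembl annotation, the same assembly. All summits lay inside the chromosome lengths. A protein-coding gene was called bound when an optimal summit lay within 500 bp on either side of its annotated 5' end. The background was all 19973 protein-coding genes of the 6 nuclear chromosomes. No annotation of ce10 was used, so ce10 lists entered only counts, overlaps and the share of summits on X. Coordinates below are 1-based on ce11. Annotated 5' ends in this species often mark the trans-splice site and lie downstream of the transcription start.

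Bound shares were compared with two-sided Fisher's exact tests, with conditional odds ratios and exact 95% intervals. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Genes and peaks are not replicates, and neighbouring genes can share a peak, so these p-values describe the list and not the spread between animals. The 13 gene lists, the tests, the distances and the rule for named genes were fixed before the data were examined. Of 556 names written in the lists, 8 matched no gene symbol. Benjamini-Hochberg adjustment was made over the 13 lists. The share of summits near 5' ends was set against 1000 uniform placements within the same chromosomes, and the smallest two-sided p these can give is 0.002. Replicates were compared at equal numbers of top peaks, with 100 circular shifts of 1 list within its chromosomes as the chance level.

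For sequence, each of 2080 6-mers, taken with its reverse complement, was counted as present or absent within 50 bp of a summit and in windows of the same size centred 300 bp to each side. An exact binomial test was made on the summits that differed, against each side, and the larger p was kept, or 1 where the sides differed in direction. Summits within 350 bp of a stronger one were left out of this test. Distances of summits to tRNA, snoRNA and snRNA genes (within 250 bp) were added after seeing the data, with 1000 circular shifts within chromosomes as the chance level.

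Named in the text by the fixed rule are oef-1 and unc-119, the 10 peaks with the highest signal, up to 4 bound members of each list by signal, up to 2 unbound members of lists bound less often than other genes, the 3 genes with the most summits in the body or 500 bp upstream, and the 3 6-mers with the smallest adjusted p. Since the 10 strongest peaks were mitochondrial, the 10 strongest nuclear peaks were named as well, a choice made after seeing the data. Other names chosen after seeing the data are marked as such.

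The list test was tested on 50 simulated sets of bound genes. Lists with a simulated share of 25% bound members were called in 99.3% of 150 cases, and lists left at the background in 0.478% of 418. Only the longer lists were raised, so germline stem cell and RNA regulators (30 members) and P granule components (25 members) never were. Raised shares below 25% were not simulated. The 6-mer test recovered 3 of 3 6-mers planted in 15% of 900 random windows and called 0 of 2080 with nothing planted. The simulated genes were drawn independently with a summit at the 5' end itself, so shared peaks and the 500 bp distance did not enter. The random windows lacked the higher GC content of real summits. These rates are therefore not the error rates of the tests on the real peaks. Alternatives changed the replicate used, the signal threshold, the distance, the definition of a bound gene, the background, the null, the overlap rule, the flanks and the build. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.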

Results

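The data describe where OEF-1, a factor known from the C. elegans germline, was recovered on chromatin in L4 hermaphrodites, the stage at which the germline grows and begins gamete formation. The optimal list held 1339 peaks, of which 1318 lay on the nuclear chromosomes and 21 on mitochondrial DNA. The median peak was 440 bp wide, and the peaks together covered 491662 bp. The lists of weak and strong candidates held 30000 rows for replicate 3 and 23600 for replicate 4. The read depth behind them is unknown. On ce10 the optimal list held 1362 peaks.

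The replicates shared most of their strong sites. Of the 1339 peaks with the highest signal in replicate 3, 841 (62.8%, 95% interval 60.2 to 65.4) had a summit within 200 bp of a summit among the top 1339 of replicate 4. Circular shifts gave a mean of 1.23% and at most 1.94%. Of the 1318 nuclear optimal summits, 1169 (88.7%) were found among the top peaks of replicate 3 and 946 (71.8%) among those of replicate 4. In the whole candidate lists, 1314 were found in replicate 3 and 1294 in replicate 4. More optimal summits were thus among the top peaks of replicate 3 than of replicate 4. As the optimal list was made from both replicates together, its recovery in either one does not measure their agreement. No chance level was set for that recovery.

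OEF-1 summits gathered upstream of protein-coding genes. Of 1318 nuclear summits, 635 (48.2%, 45.5 to 50.9) lay within 500 bp of an annotated 5' end, against a mean of 18.9% for uniform placement and at most 22.5% (permutation of summit positions, p = 0.002, the smallest 1000 placements can give). Of these 635, 500 (78.7%) lay upstream of the 5' end, with a median position of -156 bp. By annotation, 62.3% of summits fell outside coding genes, against 36.03% by placement. Introns held 21.5% against 34.2%, and coding sequence 8.35% against 25.02%. The 5' UTR held 3.11% against 1.39% and the 3' UTR 4.70% against 3.36%. Altogether 772 of 19973 protein-coding genes (3.87%) were bound, and 504 of them were also bound in the top lists of both replicates.

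**Figure D1:**
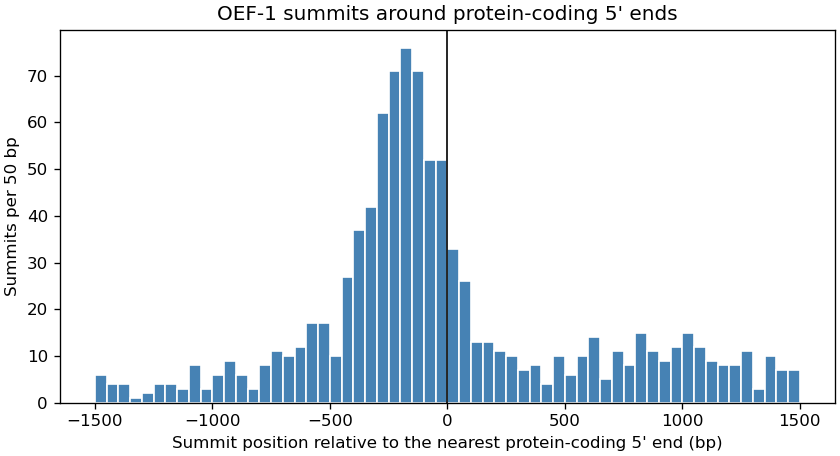
Number of nuclear summits per 50 bp (y axis) by position relative to the nearest protein-coding 5' end (x axis, bp, negative values upstream). Of the 635 summits within 500 bp, 500 lie upstream, with a median of -156 bp.

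The strongest nuclear peak (authors' signal 631) lay on chromosome III at 3867353 to 3867777, outside coding genes and 279 bp from the 5' end of rpl-3, a ribosomal protein gene. The second (611), on IV at 6117682 to 6118155, lay 285 bp from zen-4, a kinesin of cytokinesis, and within 250 bp of the snoRNA gene M03D4.78. Next came peaks nearest rpl-35 (574), drr-2 (481) and the histone gene his-68 (458). The sixth (442), on I at 13463751 to 13464217, lay in an intron 6399 bp from the nearest coding 5' end, that of ints-8, and within 250 bp of rpr-1, the RNA of RNase P. The remaining 4 were nearest Y17G9B.5 (421), cpg-1 (414), pxn-1 (379) and Y22D7AL.10 (378). The summit nearest pxn-1 lay 5660 bp from it, in an intron and within 250 bp of the snoRNA gene ZK994.7. Each of these 10 peaks was among the top peaks of both replicates. In the whole list the 10 highest signals, up to 7603, were mitochondrial.

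At oef-1 itself (WBGene00018636, IV, 7548417 to 7551519, plus strand), a peak at 7548330 to 7548562 had its summit at 7548427, in the 5' UTR and 10 bp from the 5' end, with a signal of 221. It was found in the top peaks of both replicates. The strain carries an added tagged copy of this gene, and reads from that copy and from the endogenous gene were not told apart. No optimal summit lay near unc-119, the marker gene of the strain (III, 10902641 to 10908935).

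The 3 genes with the most summits held them mostly in introns, beside small RNA genes or other genes. Inside unc-31, a neuronal gene of dense-core vesicle release, 6 summits lay within 250 bp of annotated snRNA genes. Their peaks overlapped in pairs, so there were fewer separate sites than summits. Inside glr-2, a glutamate receptor gene, 4 summits lay beside snRNA genes named sls-2, which encode spliced leader RNA 2. The annotated span of cox-6B (III, 2699663 to 2786859) held 4 summits, of which 2 were nearest cosa-1. The peaks of these 2 overlapped, as did some of those in glr-2. None of these 3 genes was bound at its own 5' end.

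Bound genes were frequent among ribosomal protein genes and in most germline lists, but not among spermatogenesis genes, and at most 1 gene of each somatic list was bound. No untagged sample was set against these sites. With Fisher's exact test, 7 of 13 lists were bound more often than other genes and 1 less often at an adjusted p under 0.05. Among the bound genes named below, rpl-20, coh-4, hrde-1, mut-15, lig-1, cdc-6, lin-54 and spe-39 had summits nearer the 5' end of another coding gene. Which gene such a peak belongs to is ambiguous.

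Ribosomal protein genes had 31 of 82 members bound (37.8%, against 3.73% of other genes; odds ratio 15.7, 95% interval 9.65 to 25.18, exact test, adjusted p = 6.61e-22). At 200 bp, 7 of the 82 were bound (8.54%, odds ratio 4.91), and at 1000 bp 48 (58.5%, odds ratio 26.5). The highest signals were at rpl-3, rpl-35, rpl-20 (421) and rpl-15 (365). The rpl-20 peak is the one given above as nearest Y17G9B.5.

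Oogenesis and maternal factors had 17 of 52 bound (32.7%; odds ratio 12.3, 6.44 to 22.7, exact test, adjusted p = 3.23e-11). They were led by cpg-1 (414), a chondroitin proteoglycan of the eggshell, with a summit 249 bp upstream on III at 4489110. Next came egg-1 (206), a receptor of the oocyte surface, and pos-1 (185) and puf-3 (177), RNA-binding proteins. Each of these 4 genes was bound in the top lists of both replicates.

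Meiotic chromosome and recombination genes had 12 of 56 bound (21.4%; odds ratio 6.87, 3.29 to 13.3, exact test, adjusted p = 4.25e-06). The strongest were coh-4 (234) and coh-3 (175), meiotic cohesins, syp-4 (233), of the synaptonemal complex, and cosa-1 (176), a crossover factor. The syp-4 summit also lay within 250 bp of an snRNA gene, H27M09.6.

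Chromatin and germline transcription regulators had 11 of 47 bound (23.4%; odds ratio 7.69, 3.52 to 15.5, exact test, adjusted p = 4.25e-06). Beside oef-1 these included lin-54 (165), lin-53 (159) and lin-9 (132), which act in repression of cell-cycle and germline genes. The ribosomal protein gene rpl-12, also on IV, was bound with the same signal as lin-54, so the same peak can count in both lists.

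Cell cycle and DNA replication genes had 8 of 57 bound (14.04%; odds ratio 4.09, 1.67 to 8.75, exact test, adjusted p = 0.00386). The clamp gene pcn-1 had the highest signal (282), followed by the ligase gene lig-1 (135), the clamp loader gene rfc-4 (134) and cdc-6 (117), of replication licensing.

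Of the P granule components, proteins of germline RNA granules, 4 of 25 were bound (odds ratio 4.76, 1.18 to 14.1, exact test, adjusted p = 0.0272). They were glh-2 (130), a Vasa-type helicase, pgl-3 (126), oma-1 (106) and znfx-1 (91.1). The last was bound in the top peaks of replicate 3 but not in those of replicate 4. The small RNA pathway had 5 of 45 bound (11.1%; odds ratio 3.12, 0.959 to 7.94, exact test, adjusted p = 0.0472), led by hrde-1 (149), a nuclear Argonaute, prde-1 (104.1), mut-15 (102) and tofu-6 (96.9).

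Germline stem cell and RNA regulators, with 3 of 30 bound, did not pass the test (odds ratio 2.77, 0.537 to 9.03, exact test, adjusted p = 0.156). The 3 were mog-4 (172), atx-2 (129) and sygl-1 (77.9), a target of Notch signalling in stem cells. Of these, sygl-1 was bound in the top peaks of replicate 3 but not in those of replicate 4. Spermatogenesis genes had 2 of 72 bound, among them spe-39 (79.6), at an odds ratio of 0.710 (0.0842 to 2.67, exact test, adjusted p = 1). Neither spe-4 nor spe-5 was bound in the optimal list, though spe-5 was among the genes bound in the top peaks of replicate 3.

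Among somatic lists, 0 of 49 muscle genes were bound, 0 of 49 intestinal genes and 0 of 56 neuronal genes. The exact intervals reach 7.25% for the lists of 49 and 6.38% for neurons, above the background of 3.87%, and the adjusted p of the exact test was 0.303 for each. Unbound members included the myosin genes unc-54 and myo-1, the vitellogenin genes vit-1 and vit-2, and the neuronal genes unc-119 and rab-3. In the cuticle collagen and hypodermis list, 1 of 193 genes was bound (0.518%; odds ratio 0.128, 0.00323 to 0.726, exact test, adjusted p = 0.0167). That gene was col-85 (103), whose summit also lay within 250 bp of a tRNA gene, and rol-6 and rol-8 were not bound.

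With the top peaks of replicate 4 alone, 4 lists remained past the threshold: ribosomal protein, oogenesis, meiotic and chromatin genes. The adjusted p of the exact test was then 0.120 for P granule components and for cell cycle genes, 0.146 for the small RNA pathway and 0.0819 for cuticle genes; the small RNA call was also lost in replicate 3 alone (adjusted p = 0.131).

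**Figure D2:**
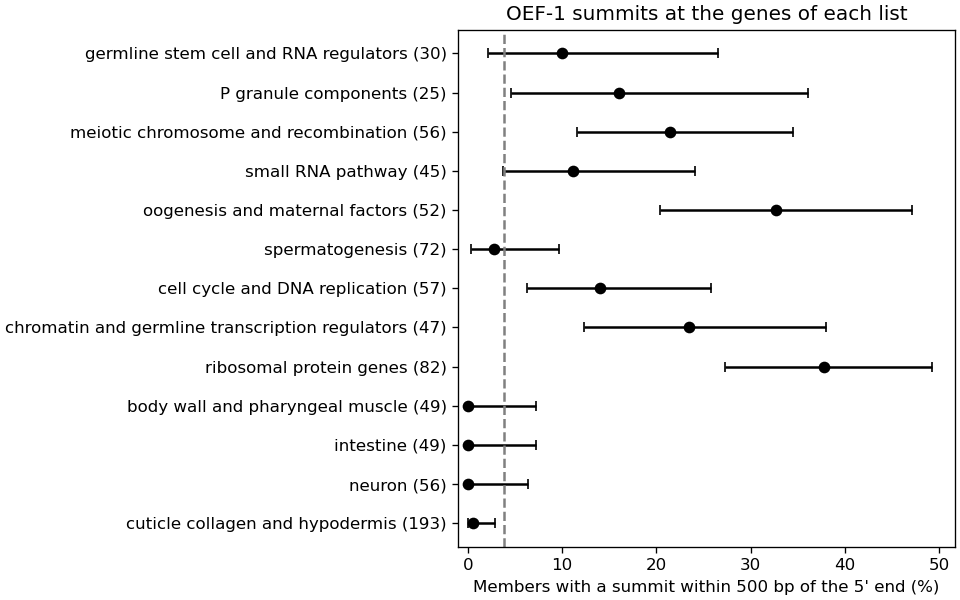
Percent of the members of each gene list (number of members in brackets) with an optimal summit within 500 bp of the 5' end; points are the shares, bars exact 95% binomial intervals, and the dashed line the share of all protein-coding genes, 3.87%. Ribosomal protein genes (37.8%) and oogenesis and maternal factors (32.7%) stand highest.

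OEF-1 summits were rare at protein-coding genes of X. On X, 9 of 2731 coding genes were bound (0.330%, 0.151 to 0.625), against 763 of 17242 on autosomes (4.43%, 4.12 to 4.74). The odds ratio was 0.0714 (0.0325 to 0.137; Fisher's exact test, p = 1.91e-37). Among autosomes the share ran from 2.58% on V to 6.53% on I. The X odds ratio was 0.0856 in replicate 4 alone and 0.0482 in replicate 3 alone. It was 0.567 (0.455 to 0.701) when each summit was given to the nearest 5' end at any distance. Arms and centres of autosomes did not differ detectably. In the outer parts of the autosomes 485 of 10672 genes were bound (4.54%) and in the centres 278 of 6570 (4.23%), at an odds ratio of 1.08 (0.925 to 1.26, Fisher's exact test, p = 0.341).

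Many summits lay at genes for small structural RNAs, a comparison added after seeing the data, and no untagged sample was set against them. Within 250 bp of a tRNA gene lay 186 of the 1318 summits (14.1%), against a mean of 3.62 and at most 15 in 1000 circular shifts (permutation p = 0.002, the smallest they can give). They marked 214 of 612 nuclear tRNA genes (35.0%). Another 98 summits lay near snoRNA genes, against a mean of 3.16, and marked 94 of 346 of these genes (27.2%). At snRNA genes, of the spliceosome and spliced leaders, there were 73 summits against a mean of 1.08, marking 50 of 129 genes (38.8%). Of the summits at tRNA, snoRNA and snRNA genes, 28, 18 and 15 also lay within 500 bp of a coding 5' end. With the top peaks of replicate 3 alone the counts were 170 for tRNA, 100 for snoRNA and 73 for snRNA genes, and with those of replicate 4 alone 184, 96 and 61.

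On X the tRNA genes held most of the summits. Of 108 X summits, 92 (85.2%) lay within 250 bp of a tRNA gene, and 106 of 276 X tRNA genes (38.4%) were marked, against 108 of 336 on autosomes (32.1%; odds ratio 1.32, 0.930 to 1.86, Fisher's exact test, p = 0.125). In replicate 4 alone that odds ratio was 1.64 (1.16 to 2.32, exact test, p = 0.00392), and in replicate 3 alone 1.32 (exact test, p = 0.118). With summits at tRNA, snoRNA and snRNA genes left out, 15 of 963 summits were on X (1.56%). Then 1 X coding gene was bound, T13C5.6, named after its value was seen. Its summit lay within 250 bp of C14F11.14, annotated as a noncoding RNA gene of a kind not left out here. Of snoRNA genes, 1 of 33 on X was marked, against 93 of 313 on autosomes (odds ratio 0.0742, 0.00180 to 0.458, Fisher's exact test, p = 3.37e-04).

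**Figure D3:**
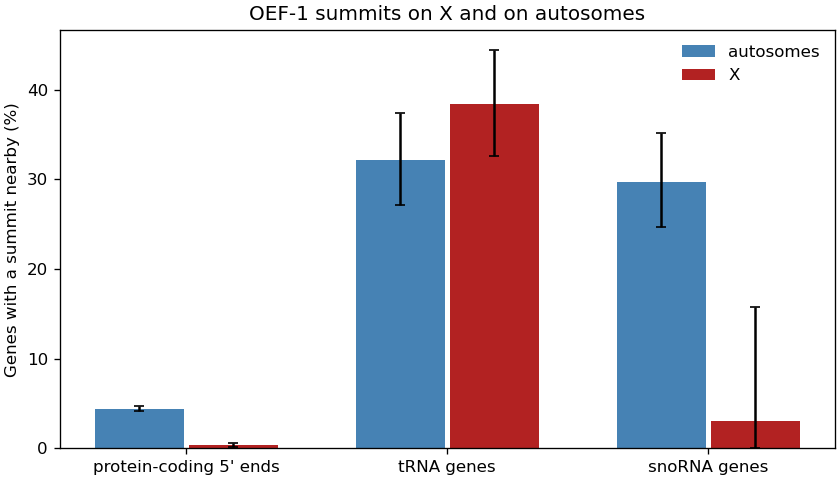
Percent of protein-coding genes with a summit within 500 bp of the 5' end, and of tRNA and snoRNA genes with a summit within 250 bp, on autosomes (blue) and X (red), with exact 95% binomial intervals. Coding genes were bound at 4.43% and 0.330%, tRNA genes marked at 32.1% and 38.4%, and snoRNA genes at 29.7% and 3.03%.

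Strong peaks lay near coding 5' ends somewhat more often than weak ones. Of the strongest 329 nuclear peaks, 174 (52.9%) lay within 500 bp of a coding 5' end, against 147 of the weakest 329 (44.7%; odds ratio 1.39, 1.01 to 1.91, Fisher's exact test, adjusted p over the pair of tests 0.0425). On X lay 11 of the strongest and 28 of the weakest (odds ratio 0.372, 0.164 to 0.788, exact test, adjusted p = 0.0150). By the same exact test, neither call held in replicate 4 alone, where the odds ratios were 1.34 (adjusted p = 0.145) and 1.04 (adjusted p = 1). For the 5' end share the odds ratio in replicate 3 alone was 1.20 (exact test, adjusted p = 0.275), and for X it was 0.162 (exact test, adjusted p = 9.02e-06). Near a tRNA gene, a count added after seeing the data, lay 20 of the strongest and 50 of the weakest peaks (odds ratio 0.362). That odds ratio was 0.742 in replicate 4 alone and 0.202 in replicate 3 alone.

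GC-rich 6-mers were frequent at summits. Of 2080 6-mers, 265 were more frequent and 144 less frequent at the 1244 summits used than in the windows on both sides (exact binomial test, adjusted p under 0.05). The smallest adjusted p belonged to GGCGCA, present at 182 summits (14.6%), against 27 and 36 of the side windows (exact test, adjusted p = 1.02e-22). Next were ACGCGC, at 140 summits against 12 and 20 windows (exact test, adjusted p = 4.41e-21), and GCGCCA, at 147 against 17 and 26 (adjusted p = 3.79e-19). The mean GC content was 43.96% at summits and 36.6% in the windows on either side. The test made no adjustment for this difference. The 192 6-mers with 5 G or C bases had a median ratio of 2 to their side windows, a summary added after seeing the data. As the named 6-mers were picked by their p, whether they exceed their GC content was not tested. In replicate 4 alone, 74 6-mers were less frequent.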

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

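The tests of tRNA gene number, of read depth on X, of the mitochondrial genome, of other samples, of single-copy tRNA genes on X and of tRNA genes with identical copies were chosen after the result was seen; those of all single-copy tRNA genes and of the raised lists were written down before their values were known.

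Peaks also appeared outside the nuclear genome and below the optimal threshold, in data that the comparisons of the report leave aside. The mitochondrial genome held 21 optimal peaks, including each of the 20 strongest in the list. Among the 1339 nuclear pooled candidates ranked just below the optimal list, 139 summits lay within 250 bp of a tRNA gene, against a mean of 3.45 and at most 11 in 1000 circular shifts. In the same candidates 16 summits lay near snoRNA genes, against at most 11, and 17 near snRNA genes, against at most 6.

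The mitochondrial peaks covered 71.3% of the 13794 bp genome, against 0.481% of the nuclear genome, in 9 distinct intervals. This breadth may reflect the many copies of mitochondrial DNA per cell as a technical source, rather than a few bound sites. Breadth alone cannot tell copy number from other broad sources, and the lists were made with a control. No biological explanation was tested, since the series has 1 group. The control alignment that would show the same regions was not analysed here.

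Summits at tRNA genes on X numbered 92. Chance overlap with tRNA genes on X does not account for them, since 1000 circular shifts gave at most 5. The shifts do not ask whether X differs from autosomes. X held 276 of the 612 nuclear tRNA genes and 92 of the 186 summits near tRNA genes, so gene number may account for its share of them. Reads shared between identical copies were tested on the 140 tRNA genes whose sequence occurs once in the nuclear genome: 22.1% had a summit, against at most 4.29% under shifts, and on X 14 of 55 such genes (25.5%), against at most 3.64%. These shares were above the shifts, but a single-copy gene can be marked by a summit at a neighbouring tRNA gene that has copies. Over all tRNA genes, 186 summits marked 214 genes. The test therefore does not decide whether shared reads are the whole source, and near-identical copies were not excluded either. Of the tRNA genes with an identical copy, 183 of 472 (38.8%) had a summit, more than of the single-copy ones (odds ratio 2.22, 1.41 to 3.58, Fisher's exact test, p = 2.65e-04), so a part from shared reads stays open. Whether tRNA genes give peaks with any tagged protein cannot be told apart from binding by OEF-1, since 0 samples with another tagged factor or no tag were used. Peaks at snoRNA and snRNA genes were not set against such samples either. A general property of open, heavily transcribed genes may therefore account for them. Peaks at coding genes, those at ribosomal protein genes among them, were not set against such samples either, so the same limit holds there.

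Few coding 5' ends on X were bound, at an odds ratio of 0.0714. Lower read depth or peak sensitivity on X would lower tRNA genes too, but their odds ratio was 1.32 with an interval of 0.930 to 1.86, above the upper bound of 0.137 for coding genes. This would argue against a loss alike across all sites of X if tRNA peaks came from reads of each gene alone. Reads shared between identical copies, not excluded above, could keep X tRNA genes marked, so the test does not decide. The snoRNA genes go the other way, with 1 of 33 on X near a summit against 93 of 313 on autosomes (odds ratio 0.0742, 0.00180 to 0.458). A loss at X sites, at tRNA genes or only at others, therefore stays open, whatever its source. A low number of genes from the raised lists on X was also tested: without the 359 members of those lists the odds ratio was 0.0797 (0.0362 to 0.152). Most bound autosomal genes, 676 of 763, lay outside those lists, as did each of the 9 bound X genes. Leaving the members out could therefore not have brought the odds ratio close to 1, and no conclusion is drawn from this test. A biological explanation may be that germline-expressed genes beyond these lists are scarce on X or silent there, which stays a hypothesis, as no expression data were used.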

How the results depend on the processing

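Of 232 alternative values of results other than single genes or single 6-mers, 183 counted as kept. These held their direction and side of the threshold, stayed within their interval or, for counts, within a set factor of the main value. Where others changed, the cause was not tested unless given. The X odds ratio kept its call under every alternative run, from 0.00853 without RNA gene summits to 0.567 for the nearest 5' end (0.416 per base, 0.264 against circular shifts). The arm comparison and the share near 5' ends (25.5% at 200 bp, 63.4% at 1000 bp) kept theirs. The top pooled candidates are the optimal list itself, so that alternative changes nothing by construction and is not counted here. The ce10 density of peaks per base on X was not run, as no ce10 lengths were used. Leaving out RNA gene summits and all alternatives for the X share of summits, for RNA gene counts and for the X odds ratios of RNA genes were chosen after seeing the data.

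With 1 replicate left out, odds ratios ran from 3.32 to 9.91 for P granule components, 2.38 to 2.47 for the small RNA pathway, 2.35 to 4.16 for cell cycle, 0.131 to 0.253 for cuticle, 3.75 to 3.90 for stem cell regulators (past the threshold without replicate 4) and 0.694 to 1.10 for spermatogenesis. Raised lists numbered 4 to 7 and lowered ones 0 to 1. Strong against weak peaks gave 1.20 to 1.34 near 5' ends and 0.162 to 1.04 on X, and 74 to 121 6-mers were less frequent.

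With the stronger peaks only, which removes peaks by construction, 669 peaks remained, covering 219197 bp, with 65 summits at tRNA genes, 5.25% of summits on X, 156 6-mers more and 69 less frequent; the small RNA odds ratio was 2.26, that of cuticle 0, and 0 lists were lowered. At 200 bp, where fewer genes are bound, P granule (2.16), small RNA (2.42), cell cycle (2.89) and cuticle (0) lost their calls, leaving 4 raised and 0 lowered. Of these 4, ribosomal protein genes fell to 4.91 and oogenesis to 6.85, with meiotic genes highest at 10.1 and chromatin regulators at 7.69. Calls of single named genes depended on this distance too. At 200 bp rpl-3, rpl-35, rpl-20, rpl-15, cpg-1, pos-1, puf-3 and pcn-1 were among those no longer bound, while oef-1, egg-1, coh-3 and coh-4 were among those still bound. At 1000 bp ribosomal protein genes rose to 26.5 and spermatogenesis turned to 1.34. Counting gene bodies raised stem cell regulators to 3.60, past the threshold, and neurons to 1.02. Assigning the nearest 5' end gave small RNA 1.57, cuticle 0.692, neurons 1.58 and 0 lowered lists. On autosomes alone small RNA was at 2.85 (exact test, adjusted p = 0.0654). Against circular shifts, which move summits off promoters and so lower the chance level for any list, the ratio was 7.85 for stem cell regulators, now past the threshold, 2.099 for spermatogenesis and 0.405 for cuticle, with 0 lowered.

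Shared top peaks were 56.5% with summits within 100 bp and 51.8% with a reciprocal overlap of 50%. The strong against weak odds ratio near 5' ends was 1.21 over the list split at its middle and 1.39 at 1000 bp, both no longer past the threshold. The odds ratio of tRNA genes on X passed the threshold without replicate 3 (1.64, exact test, p = 0.00392), against 1.32 without replicate 4, and at 500 bp (1.41, exact test, p = 0.0438), and that of snoRNA genes kept its call throughout. Without RNA gene summits, 1.56% of summits lay on X, the strong against weak ratio on X was 0 (exact test, adjusted p = 0.0612), and 167 6-mers were more and 63 less frequent.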

Other observations

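The test of gene classes below was written down before its values were known; the counts at piRNA, miRNA and lincRNA genes, pseudogenes and tRNA families were chosen after seeing the data.

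Genes that share the first part of their symbol were compared as classes. Over 419 classes of at least 5 genes (Fisher's exact test, Benjamini-Hochberg over the classes), 7 were bound more often than other genes. Of these, 3 hold no gene of the fixed lists, as the hypothesis that other classes share OEF-1 sites predicted. The eef genes, of translation elongation, had 5 of 6 members bound (odds ratio 125, 95% interval 13.97 to 5920, exact test, adjusted p = 6.91e-05): eef-1A.1, eef-1B.1, eef-1B.2, eef-1G and eef-2. The dnj genes, of J-domain co-chaperones, had 7 of 29 bound (odds ratio 7.97, 2.87 to 19.4, exact test, adjusted p = 0.00779). The npp genes, of the nuclear pore, had 6 of 26 bound (odds ratio 7.51, 2.46 to 19.5, exact test, adjusted p = 0.0271), among them npp-3, npp-6 and npp-9. In the top peaks of single replicates the bound members numbered 4 and 5 for eef, 6 and 5 for dnj, and 5 and 7 for npp, in replicates 3 and 4. No class was bound less often past the threshold; the chemoreceptor class str came closest, with 0 of 193 bound (exact test, adjusted p = 0.0522).

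Summits were fewer than circular shifts gave at piRNA genes (32, against a mean of 59.8 and at least 36) and at pseudogenes (23, against a mean of 53.6 and at least 32). At miRNA genes there were 7, against a mean of 1.78 and at most 9, and at lincRNA genes 5, against a mean of 4.39 and at most 16.

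Of 57 families of tRNA genes with identical sequence, 41 had some but not all members near a summit, 14 had none and 2 had all.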
